A study of Schizosaccharomyces pombe with 22 samples.

How the data were processed

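RNA and immunoprecipitated DNA of Schizosaccharomyces pombe were hybridised to spotted arrays with ORF or IGR probes, mostly in duplicate spot sets. The deposited scanner files give a median signal intensity and a local background intensity per spot for 1 channel and 1 spot set. Labels name published protocols for expression profiling and for chromatin immunoprecipitation on arrays. The scanner, software and filters are not given in the sources used here. The authors' value tables hold log2 values with a floor, whose centring and direction are unknown, and were used as an alternative. Their medians ranged from -6.64, the floor, for channels of the beads experiment to 0.88 for replicate 1 of Pst3-GFP over input. The IGR and ChIP files also hold the authors' reference intensity per region, the same for every array of a probe set. A header for IGR probes names it as a wild-type median, while the other headers, that for ORF probes among them, name no strain.

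Samples were grouped by their labels. The planned test of pst3 ratios against 0 was not possible because each array labelled pst3 repressed was used through 1 deposited channel, labelled Cy5 for 1 array and Cy3 for the other. These 2 arrays were instead compared with the 8 wild-type arrays as single-channel log2 levels, with quantile normalization in place of the planned loess within array. Both may come from 1 RNA extract. Background was corrected with normexp and an offset of 50, except in channels whose deposited background was 0 for at least 90% of spots, and control spots were left out afterwards. Spot sets were averaged, channels were quantile normalized, channels of 1 array were averaged, and limma's lmFit and eBayes were applied with Benjamini-Hochberg adjustment at 0.05.

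Names of 192 probes from 2 plates were left out because they appeared exchanged on the print of the arrays labelled pst3 repressed. This choice was made after seeing the data and was prompted by the largest differences. Also left out were 21 features not above empty spots. Of the 192 names 189 were on all arrays, and some features fell under both rules or were not on all arrays. Of 4716 genes on all arrays 4510 were tested. Wild-type replicates 1 to 5 and 6 to 8 lay on separate prints. For ratios between wild-type channels, loess within array was used on the 7 arrays with both channels, and replicate 1, with 1 channel, was left out.

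For chromatin arrays, signals as given were divided by the authors' reference, log2 transformed and centred on the median without loess. The joint fit planned with the beads experiment could not be made, because that experiment was 1 slide, so the 2 arrays over wild-type input were fitted alone with limma. For the same reason the tests planned for the beads slide were replaced by counts of at least 2-fold differences and by percentiles among random lists. Several of these settings had been looked at before the main one was kept as planned. For the H3 arrays, differences were counted where both spot sets exceeded 1 on the log2 scale.

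Gene lists, fixed before the data were examined except that subtelomere membership (within 100 kb of the ends of chromosomes I and II) was computed from the annotation, were tested with limma's cameraPR. Estimated correlations and fry served as alternatives. A planned list of centromere-proximal genes was not tested. Named genes were, by a rule also fixed before, pst3, pst1, pst2 and clr6, the 10 largest rises and falls past the threshold with the same sign in every array and spot set, and up to 4 members per list with the smallest p. Of 5060 ORF probe names 4778 matched the reference annotation, and of 4941 IGR names 4714.

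The alternatives were other background corrections, median centring or loess, leaving out dim probes, single spot sets, leaving out each array, the wild-type prints alone and the print as a random block. On data simulated for the expression comparison with 4510 genes, 4%, 42%, 84% and 92% of genes changed by 1, 2, 3 and 4 on the log2 scale were called, and 8 of the 119 called genes were unchanged ones. On data simulated for the IGR comparison with 4927 regions, 22% of regions changed by 2 and 94% of those changed by 4 were called. On data simulated for the wild-type ratios, 98% of genes changed by 1 were called. The simulated noise was normal and independent between genes and arrays. It held no print effect, no shared reference and no signal floor, so these shares do not give the accuracy of the real comparisons. Analyses used R 4.3.3 with limma 3.58.1 and Python 3.11.15.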

Results

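RNA levels and chromatin immunoprecipitates of the fission yeast Schizosaccharomyces pombe were measured on spotted arrays with probes for open reading frames (ORFs) or for intergenic regions (IGRs). The study concerned Pst3, a homolog of Sin3, which is the scaffold of histone deacetylase complexes, and its title names the nucleolus, the site of ribosome synthesis. Of the 22 samples, 2 held RNA of a strain with pst3 under a repressible nmt promoter, labelled as repressed, and 8 held wild-type RNA. A further 2 samples compared DNA bound by green fluorescent protein-tagged Pst3 (Pst3-GFP) with wild-type input on IGR probes. There were 4 samples from a Pst3-GFP experiment with beads, 2 on IGR and 2 on ORF probes. The last 6 came from histone H3 immunoprecipitations in wild type and in strains named hst2D and hst4D, 1 per strain and probe set. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Codes in the wild-type array titles recur in pairs of arrays, mostly across the prints, and what they name is not given. The 8 wild-type arrays may therefore not be separate samples. The number of arrays limits the precision. Median net ORF signals of the arrays labelled pst3 repressed were 1571 for replicate 1 and 3651 for replicate 2.

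The expression comparison asked which genes differed when pst3 was repressed. Transcripts of gas1, a cell wall glucanosyltransferase, were higher on the arrays labelled pst3 repressed than on wild-type arrays by 6.20 on the log2 scale (SE 0.54). On replicate 2 labelled pst3 repressed its net signal was 65521, near the scanner maximum, so this size is not exact. Transcripts of rdp1 (spac6f12.09), the RNA-directed RNA polymerase of the RNA interference pathway, were higher by 4.55 (SE 0.49). The rdp1 probe did not exceed the 95th percentile of empty spots on any wild-type array, so its rise is measured from the floor. Transcripts of rps1901, a protein of the small ribosomal subunit, fell by 3.99 (SE 0.37). Genes of nucleolar proteins and ribosomal RNA processing fell as a group. Tf2 retrotransposons passed limma's list test (adjusted p = 0.00546) but not with an estimated correlation (adjusted p = 0.168), and 8 of 9 elements did not pass on their own. With 2 against 8 arrays, limma with Benjamini-Hochberg adjustment called 402 of 4510 genes at 0.05, of which 205 were higher and 197 lower. The arrays labelled pst3 repressed lay on an array print of their own, and with the print as a random block, which cannot remove an effect of that print, 138 genes were called, 83 of them higher. Without replicate 1 of the arrays labelled pst3 repressed 35 genes were called, without replicate 2, 77, and with median centring in place of quantile normalization, 175.

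The pst3 probe itself did not differ. Its log2 level was 10.15 ± 0.10 (SD, n = 2) on the arrays labelled pst3 repressed and 10.21 ± 0.38 (SD, n = 8) on wild-type arrays. The difference was -0.05 (SE 0.39, limma adjusted p = 0.959). The 1 deposited channel of each array labelled pst3 repressed was taken as RNA of the repressed strain, which could not be checked here. Measured pst3 thus did not show the repression that the label names. The net signal of pst3 exceeded the 95th percentile of empty spots on every array. On replicate 2 labelled pst3 repressed this limit was 4.5, and only 8 of 4510 genes did not exceed it, so passing it says little there. On that array pst3 (3460.5) lay above the Escherichia coli control medians (370.5 to 954.5) but below that of luciferase (10002.5). Whether the pst3 signal is specific was not tested. Its homologs pst1 (0.68, SE 0.65, limma adjusted p = 0.567) and pst2 (-0.00, SE 0.64, limma adjusted p = 1.00) and the deacetylase gene clr6 (-0.38, SE 0.65, limma adjusted p = 0.774) did not pass the test either. Against wild-type replicates 6 to 8 alone pst1 passed (1.82, limma adjusted p = 0.0189), and against replicates 1 to 5 alone its difference was -0.00308. Among the 7 measured genes repressed by thiamine, the vitamin that shuts off nmt promoters, thi2 rose by 1.89 and pho4, an acid phosphatase, fell by 1.62, while nmt1 had a difference of 1.38 (limma adjusted p = 0.0612). The list of these genes did not shift (adjusted p = 0.900), and 4 members were called when adjusted over the list alone.

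Among the largest rises after gas1 were SPBC19C7.04c (6.07), SPAC1705.02 (5.22), cmt1 (5.21), SPAC1348.06c (4.94), SPAC977.05c (4.88), SPCC70.08c (4.56) and aca1 (4.54), and the probe b8647-5, not matched to a gene here, rose by 5.12. Both arrays labelled pst3 repressed lay above all 8 wild-type arrays for each of these. The largest falls were SPBC21D10.08c (-5.67), SPBC12C2.01c (-5.08), rps1901 (-3.99), SPCC191.03c (-3.80), leu2 (-3.76), an enzyme of leucine synthesis, hpt1 (-3.74), SPBC12C2.14c (-3.74), pdx3 (-3.70), SPAC22E12.12 (-3.60) and SPBC365.04c (-3.49). Their limma adjusted p-values ranged from 4.16e-06 for SPBC21D10.08c to 0.0254 for SPCC191.03c, with n = 2 and n = 8. Without replicate 1 of the arrays labelled pst3 repressed SPAC1705.02 (4.95, limma adjusted p = 0.0894), SPCC191.03c (-5.06, 0.0889), leu2 (-2.94, 0.117), pdx3 (-3.70, 0.0579) and SPBC365.04c (-3.58, 0.195) did not pass. Without replicate 2 SPCC191.03c (-2.54, limma adjusted p = 0.331) and SPBC365.04c (-3.40, 0.167) did not pass. The sizes and their order are not exact, because on replicate 1 labelled pst3 repressed 8 of the 10 largest falls, all but rps1901 and SPCC191.03c, did not exceed the 95th percentile of empty spots, as held for 118 of the 197 lower genes and 1085 of all 4510. On replicate 2 this held for SPCC191.03c and pdx3. The limit there was 4.5, while Escherichia coli control spots had median net signals of 370.5 to 954.5. Net signals of hpt1 (154) and SPBC12C2.14c (260) lay below all of these medians, and that of SPBC365.04c (820.5) below the highest. On the same array gas1 and cmt1 lay near the scanner maximum. On each of wild-type replicates 6 and 8, 8 of the 10 largest rises did not exceed empty spots.

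Of 83 measured nucleolar and ribosomal RNA processing genes, 10 fell, 0 rose and 73 did not pass the test, with a median difference of -0.71. Examples were rrp14 (-2.79), utp3 (-2.68) and ebp2 (-2.26), while rrp9 fell by 2.0. Adjusted over the list alone, 13 members passed, 12 of them lower. The list shifted downward in limma's cameraPR with a preset correlation of 0.01 (adjusted p = 0.000605 over 22 lists) and also with an estimated correlation (adjusted p = 0.00813). Against wild-type replicates 1 to 5 alone its adjusted p was 0.00137, and against replicates 6 to 8 alone 0.00198. This list was drawn up with the study's title in view.

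Of 9 measured Tf2 elements, Tf2-3 rose by 1.94 (SE 0.56) and 8 did not pass the test, with a median difference of 1.15, and 4 were higher when adjusted over the list alone. Their cameraPR adjusted p was 0.00546, which was lost with an estimated correlation (adjusted p = 0.168) and against wild-type replicates 1 to 5 alone (adjusted p = 0.0521). The elements are near-identical copies whose probes can share signal, so their values are not independent.

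None of the other lists passed cameraPR. With fry, strain markers (adjusted p = 0.00295), RNA polymerase I (0.00348), stress response (0.0128), respiratory chain (0.0143) and G1 to S transition (0.0197) also passed. In the test with an estimated correlation the lowest adjusted p of these lists was 0.168, for the respiratory chain. Of 131 cytosolic ribosomal protein genes 10 fell and 1 rose (list adjusted p = 0.153, or 0.0119 and downward against wild-type replicates 6 to 8 alone and 0.576 against 1 to 5 alone), and rps001 (-2.33), rps1001 (-2.14) and rpl7-3 (-2.40) were among those lower, with 11 called when adjusted over the list alone. Among 11 RNA polymerase I genes rpa49 fell by 1.35 (list adjusted p = 0.153, 1 adjusted over the list alone). In the respiratory chain cox8 rose by 2.16 and atp7 by 1.54, while atp3 fell by 1.91 (24 genes, list adjusted p = 0.153, 5 adjusted over the list alone). Of 22 stress response genes the glutaredoxin gene grx1 rose by 3.27 and rds1 fell by 2.08 (list adjusted p = 0.153, 2 adjusted over the list alone).

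In the nitrogen starvation and mating list, isp6, a vacuolar protease, rose by 3.10, the meiotic regulator mei2 by 1.73 and the pheromone G protein gene gpa1 by 1.63, while the agglutinin gene map4 fell by 2.53 (20 genes, list adjusted p = 0.287, 4 adjusted over the list alone). Of 123 meiotic genes 6 rose and 5 fell (list adjusted p = 0.376, 12 adjusted over the list alone), with mug151 (3.38), mcp6 (3.24) and mug122 (2.68) higher and num1 (-2.39) lower. The glycolysis list (adjusted p = 0.385, 3 adjusted over the list alone) held higher adh4 (3.48), an alcohol dehydrogenase gene, and pgi1 (2.08). Of the iron uptake list (adjusted p = 0.385, 2 adjusted over the list alone) the siderophore transporter gene str1 fell by 3.40 and the copper transporter gene ctr4 by 2.54. The hexose transporter gene ght5 rose by 2.42 in a list with adjusted p = 0.900 and 4 adjusted over the list alone.

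Among genes for chromatin proteins, rxt2, a subunit gene of a Clr6 complex, rose by 2.76 (Sin3 complex list adjusted p = 0.618, 1 adjusted over the list alone). The sirtuin gene hst2 rose by 1.96 and the deacetylase gene clr3 fell by 1.61 (list adjusted p = 0.900, 2 adjusted over the list alone), and the centromeric histone gene cnp1 fell by 1.70 (histone list adjusted p = 0.385, 1 adjusted over the list alone). Of 64 subtelomeric genes 3 rose, among them yhb1 (3.27), and 1 fell (list adjusted p = 0.385, 4 adjusted over the list alone). The list of mitosis and cytokinesis (adjusted p = 0.153, 0 adjusted over the list alone) held lower adg3 (-1.35), and that of the G1 to S transition (adjusted p = 0.588, 2 adjusted over the list alone) held lower pof3 (-1.94). Strain markers (adjusted p = 0.153, 1 adjusted over the list alone), proteasome (adjusted p = 0.377, 0), heat shock (adjusted p = 0.718, 0) and phosphate (adjusted p = 0.900, 0) held no gene called over all genes tested.

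**Figure D1:**
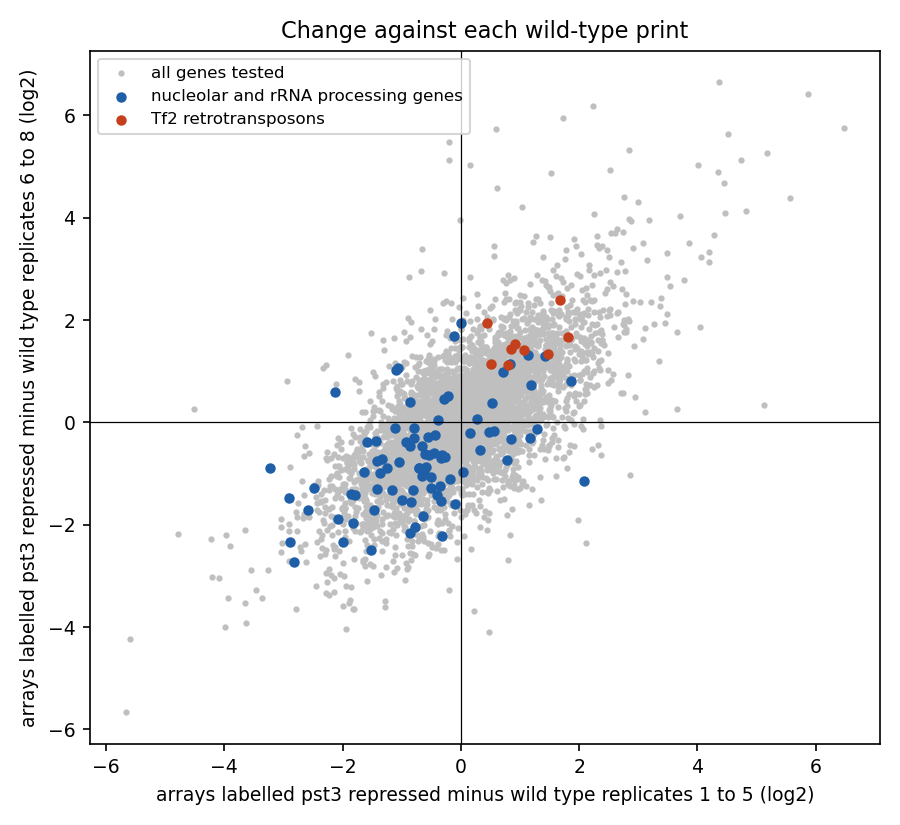
Log2 difference of each of 4510 genes between the arrays labelled pst3 repressed and wild-type replicates 1 to 5 (x axis) or 6 to 8 (y axis), each point a gene, with nucleolar genes in blue and Tf2 elements in red. The differences correlate across genes (r = 0.683), partly because both share the arrays labelled pst3 repressed, and genes are not independent replicates.

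By size alone, 1387 genes differed at least 2-fold in the same direction on both arrays labelled pst3 repressed, 713 higher and 674 lower. The same rule applied to pairs of wild-type arrays against the others gave a median of 440 genes over 28 pairs, with a range from 158 to 1094. In the limma test these pairs called a median of 0 genes and at most 44. None of them lay on the print of the arrays labelled pst3 repressed, so they hold no effect of that print. In the authors' values 1020 of 7232 spots met the rule with the same sign in both columns and 763 after 1 column was turned, and the columns correlated at r = 0.0471. Against both wild-type prints separately, 322 genes were called in the same direction, 184 higher and 138 lower. Both comparisons share the arrays labelled pst3 repressed, so overlap arises without any effect of pst3. The wild-type prints themselves differed at 484 genes in limma with Benjamini-Hochberg adjustment, 207 of them higher on the print of replicates 6 to 8.

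The wild-type arrays with both channels deposited gave the background of the assay. One gene, mei3, an inducer of meiosis, had a mean log2 ratio of 0.57 between the channels (SE 0.07, limma adjusted p = 0.0399, n = 7). No other of the 4858 genes passed limma with Benjamini-Hochberg adjustment, and 782 had an unadjusted p under 0.05. The ratio of pst3 was -0.16 (SE 0.10, limma adjusted p = 0.408, n = 7). Which deposited channel held which dye is not given in the sources used here, and over the 64 ways of turning the arrays 0 to 3 genes were called. With the print as a block 17 genes were called, with replicates 6 to 8 alone 36, and without any 1 array 0.

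The Pst3-GFP comparison with wild-type input asked which intergenic regions were bound by Pst3. The regions named for mse1 (4.80), pro3 (4.63), cid16 (4.30), pex32 (4.12), rbx1 (4.08), rpl30 (3.90), dss1 (3.88), cam1 (3.83), nup107 (3.75) and lyr3 (3.57) had the highest mean log2 ratios of immunoprecipitate over reference. The lowest were those of git5 (-4.56), isp4 (-4.51), mrpl31 (-4.44), mug86 (-4.35), mug115 (-4.28), rpl3601 (-4.14), fol2 (-3.83), SPCC794.04c (-3.79), air1 (-3.71) and SPAC22E12.18 (-3.69). These sizes and their order are not exact, because signals lay near background. On replicate 2 none of the 10 highest regions had a net signal above the 95th percentile of spots named as missing, a limit that 3234 of all 4927 regions did not exceed there. The lowest means rest more on replicate 1 (git5 -7.07, against -2.05 on replicate 2), where 5 of the 10 lowest regions, mug86, fol2, air1, rpl3601 and SPAC22E12.18, did not exceed missing spots. Each mean had an SE of 0.84, shared by all regions, with n = 2 arrays. A call therefore reflects the size of the mean and not how well the arrays agreed for that region. The IGR of rpl3601, for one, was called with -7.36 on replicate 1 and -0.91 on replicate 2. The 1 deposited channel of each array was taken as the immunoprecipitate. Of 4927 regions limma with Benjamini-Hochberg adjustment called 86, 49 above and 37 below the reference, of which 40 and 29 did not exceed missing spots on replicate 2, and 467 had an unadjusted p under 0.05. The count was 642 after normexp correction, 35 and 0 with the first and second spot set alone, and 0 with background subtracted. With the dimmest 25% of regions left out it was 100, 21 above and 79 below, of which 17 were among the 86. With normexp the mean of mse1 was 3.03, and with normexp and loess it was 0.96 (limma adjusted p = 0.267), that of pro3 0.61 (0.595) and that of rbx1 0.28 (0.766). All 49 regions called above had a reference signal below the median of 667, and the ratio of replicate 2 had a rank correlation of -0.912 with the reference. Both ratios share this reference, and their correlation across regions (r = 0.208) compares with a median of 0.117 when signals were exchanged between regions of like reference.

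The IGR of swi6, the heterochromatin protein HP1, was called above at 3.06 (limma adjusted p = 0.0231, n = 2), and that of snu13, a nucleolar ribonucleoprotein, at 2.96 (limma adjusted p = 0.0303, n = 2). In the heat shock list the IGR of hsp20 was called at 3.45, and in the hexose list that of fbp1, a gluconeogenic enzyme, at -3.67. In the RNA polymerase I list that of rpa2 was called below at -2.92 (limma adjusted p = 0.0339, n = 2). Those of adg3 (2.91) and SPBPB2B2.05 (2.85) were called above. Of the meiotic list 2 regions were called above and 2 below. In the list that holds swi6, 1 of 12 regions was called. Reference signals of swi6, snu13 and hsp20 lay at percentiles 2.02, 1.24 and 1.62 of all regions, within the low range of regions called above. The regions of pst3 (-0.47), pst1 (-0.48), pst2 (-0.20) and clr6 (0.35) did not pass the test. No list of 21 passed cameraPR, the lowest adjusted p being 0.157 for hexose transport, and nucleolar regions had a median of 0.02 (adjusted p = 0.932, 1 of 86 members called, and 1 adjusted over the list alone).

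**Figure D2:**
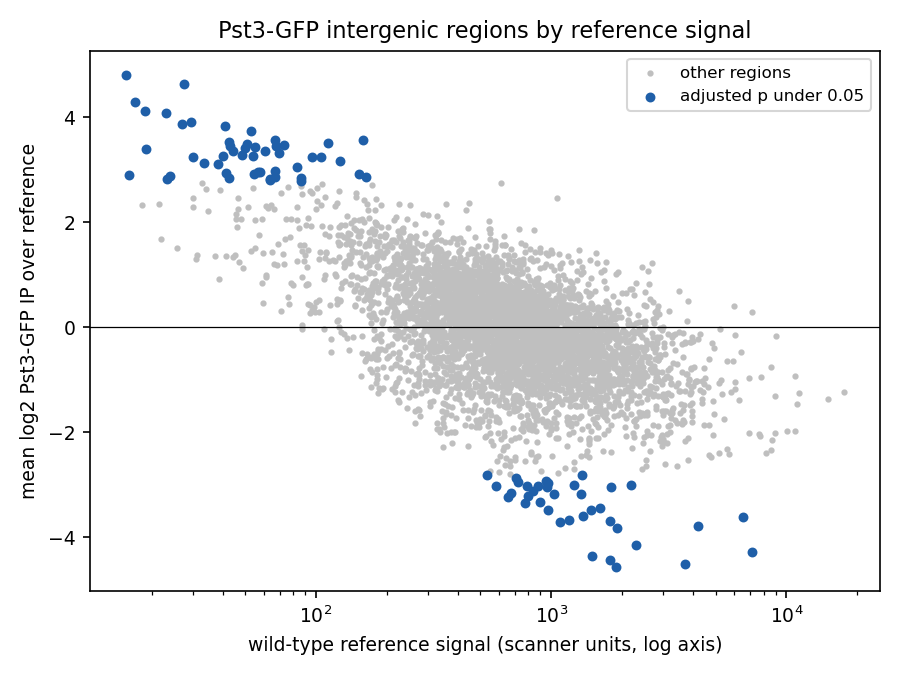
Mean log2 ratio of Pst3-GFP immunoprecipitate over reference for 4927 intergenic regions (y axis) against the wild-type reference signal in scanner units (x axis, log scale), each point a region and the 86 called regions in blue. The 49 regions called above lie at low reference signals, with a median of 53.

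The experiment with beads consisted of 1 slide, deposited as channels named 7-3 and 7-5, so it had no replicate and no test. The ORFs of wtf11 (5.46), tup1 (5.20), utp18 (4.94) and rit1 (4.90) had the highest log2 ratio of 7-5 over 7-3, and those of edc1 (-8.30), ggt1 (-8.12), cmt1 (-7.93) and arg82 (-7.89) the lowest. In IGRs the highest was npt1 (5.56) and the lowest eap1 (-7.53). At least 2-fold differences held for 260 ORFs above and 1337 below of 4880, and for 107 IGRs above and 1092 below of 4940. Channel 7-5 of wtf11 stood at 16 on the log2 scale, the scanner maximum, and that of edc1 (9.49) and ggt1 (10.03) near background, so such ratios and their order are not exact. The median net signal of channel 7-5 was below 0 on both probe sets, and which direction of the ratio is that of bound DNA is not settled. Among 10000 random lists the medians of the fixed gene lists had percentiles from 8.66 for hexose transport to 95.6 for meiotic genes, or 91.3 and 4.38 with the ratio turned. The beads ratio correlated with log2 channel 7-3 at r = -0.901 on IGR and -0.906 on ORF probes. With channel 7-5 the values were 0.273 and 0.296, so the ratio mostly follows channel 7-3. Across regions it correlated with the ratio over wild-type input at r = 0.0889 and rho = 0.112. That r was 0.267 without replicate 1 and -0.0688 without replicate 2 of the arrays over input. The denominators of these ratios, the log2 reference and channel 7-3, correlated at r = 0.385, so the agreement cannot show shared binding. Regions are not independent replicates.

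The H3 arrays asked whether H3 differed between hst2D, hst4D and wild type, with 1 array per strain and so no replicate check. Whether the deposited channel held H3-bound DNA or input is not settled by the labels, so the differences carry no direction for H3. The IGR of skb5 was lower than wild type in hst2D (-3.32) and hst4D (-3.31), and that of nop52, a nucleolar protein, in hst2D (-1.95) and hst4D (-1.94). Both mutants were set against the same wild-type array, and their IGR signals had rank correlations of 0.173 (hst2D) and 0.190 (hst4D) between spot sets, so the likeness of their differences is not evidence of a shared change. Among ORFs, pmc3 (-2.61 in hst2D, -2.66 in hst4D) and SPAC17C9.11c (-2.43 and -2.39) were lowest. At least 2-fold differences in both spot sets held for 12 IGRs and 26 ORFs in hst2D and for 21 IGRs and 28 ORFs in hst4D against wild type. Between hst4D and hst2D no IGR or ORF met that rule, while in the authors' values 2798 of 5335 IGR spots and 2082 of 4020 ORF spots differed at least 2-fold. Of the ORFs, 71 exceeded 2-fold with opposite signs in the spot sets, whose differences correlated at r = -0.465. Median ORF signals of sets 1 and 2 were 613 and 742 in hst2D but 746 and 614 in hst4D. Rank correlations of signals between the strains were 0.315 and 0.506 for sets of unlike number and 0.271 and 0.251 for sets of like number. The set numbers may therefore be crossed between the strains, and with the spot sets paired by signal level 0 ORFs met the rule. Per the labels the H3 immunoprecipitate carried Cy3 for wild type and Cy5 for both mutants, and signals on the mutant arrays lay near those of spots named as missing (median net 97.5 for regions and 87.3 for missing spots on IGR set 1 of hst2D).

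Genes beside the 5% of IGRs with the highest Pst3-GFP ratio were compared with others on the arrays labelled pst3 repressed. The 212 genes had a median difference higher by 0.14 than the others (two-sided permutation test over genes, p = 0.0915, adjusted p = 0.183). The difference was -0.04 for the top 10% and -0.01 without replicate 2 of the Pst3-GFP arrays. For ORFs of the beads slide the 225 genes with the highest ratio differed by -0.03 (permutation p = 0.681, adjusted p = 0.681), and with the ratio turned by 0.08 (permutation p = 0.280). Genes are not independent replicates.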

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

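The tests on prints, on plates and on the shared reference were chosen after the results were seen, and the test of probe brightness was chosen before.

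The first pattern is the 402 genes called between the arrays labelled pst3 repressed and wild type. A difference between array prints may account for many of them, since the wild-type prints called 484 genes against each other, and only the real split among the 56 splits of the 8 wild-type arrays gave as many (1 split, highest of the others 1 gene), which argues against chance as the source of the print difference. Repression of pst3 stays open because these arrays share no print with wild type, and the pst3 probe did not fall. With the print as a random block 138 genes were called, but this block cannot remove an effect of a print that holds only these arrays. For the lower nucleolar genes the larger cameraPR adjusted p against either wild-type print alone was 0.00198. Their median difference moved by 0.0973 between the wild-type prints, against -0.708 on the arrays labelled pst3 repressed. Between the wild-type prints this list did not pass (cameraPR adjusted p = 0.903). The print of the arrays labelled pst3 repressed holds no wild type, so a print effect and repression cannot be told apart for this list either.

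The second pattern is that the largest differences first seen lay at names of 2 plates. On the arrays labelled pst3 repressed, the levels of these names had a rank correlation of 0.0385 and 0.0462 with wild-type levels of the same names. With the names exchanged between the plates the correlations were 0.646 and 0.673, which is consistent with an exchange of names on that print. A true change of these genes is argued against by the same 0.646.

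The third pattern is the 86 intergenic regions called with Pst3-GFP. The shared reference as the only source of these calls is argued against. Of 100 draws that exchanged signals between regions of like reference, 0 gave as many calls (median 0, highest 65). A part played by the reference stays open. With an unadjusted limma p under 0.05 the draws had a median of 335 regions, against 467 observed. These draws used signals without background correction, and with background subtracted 0 of 3482 regions were called. Probe brightness may contribute, and the test was not decisive: at a given reference the Pst3-GFP signal had a rank correlation of -0.0785 with the H3 wild-type signal (-0.0521 for replicate 1 and -0.176 for replicate 2), while it was 0.167 with channel 7-3 of the beads slide, a comparison with no bound set beforehand. Binding by Pst3 was not tested separately and stays open.

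Of 113 groups of wild-type values 13 held a sample far from the others, and chance flags about 1 in 20 groups. Replicate 5 had 5.99% of genes at least 2-fold apart between channels, against 0.350% to 1.87% on other arrays. Replicate 3 was lowest for clr6 (7.81), tpi1 (12.66) and mug122 (8.81). Replicate 1 was lowest for rpa34 (10.69), mts4 (8.83), leu1 (12.21), hsp9 (8.89) and Tf2-5 (8.40). Replicate 7 was highest for hpt1 (12.89) and pho4 (12.59) and lowest for SPBC365.04c (8.47), and replicate 8 was lowest for ura4 (8.95), all as log2 levels.

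Foreign control spots, not used in any comparison, exceeded the 95th percentile of empty spots in 10 of 28 medians. Luciferase spots had a median net intensity of 851.8 on replicate 1 labelled pst3 repressed and 10002.5 on replicate 2. Escherichia coli spots of kinds 1, 2 and 3 had 507.8, 370.5 and 954.5 on replicate 2. On the wild-type H3 ORF array kinds 1 and 2 had 2153.8 and 426.5, and kind 1 had 407.5 on hst2D, 395.3 on hst4D and 33.5 on channel 7-3 of the beads slide.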

How the results depend on the processing

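For the arrays labelled pst3 repressed, the settings for single wild-type prints, the random block, arrays that stand apart, leaving out each wild-type array and plate names were chosen after seeing the data, as were subtracted background and normexp with loess for Pst3-GFP, normexp for its lists and for binding, the turned beads ratio and the H3 spot sets paired by signal level. Of the 20 genes with the largest differences, 15 stayed past the threshold in all 21 settings, and of the 20 regions 0 did so in 7. Over single genes 472 settings kept direction and side of the threshold, 12 were weaker, 1 was stronger and 18 reversed, and the causes were not tested. No paired analysis was possible because the labels pair no pst3 array with a wild-type array. Few arrays, and signals near background on the H3 and beads arrays, limit precision.

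The 402 genes became 175 with median centring, 696 and 818 with wild-type replicates 1 to 5 or 6 to 8 only, and 138 with the print as a random block. Without the 3 wild-type arrays that stand apart (replicates 1, 3 and 7) the count was 660. With the plate names as deposited 504 of 4697 genes were called, and with the names exchanged back 405 of 4697. Leaving out 1 array labelled pst3 repressed gave 35 to 77 genes, with the lone array assumed to vary like the others, and 1 wild-type array 283 to 521. The 2-fold count ranged from 1469 to 1616 and from 1382 to 1432. The 2 called lists became 1 with wild-type replicates 1 to 5 only, 1 with an estimated correlation and 7 with fry, and leaving out arrays gave 2 to 3.

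The difference of pst3 reversed to 0.0481 with spot set 1 and 0.12 with wild-type replicates 1 to 5 only, and ranged from -0.12 to 0.02 without 1 array labelled pst3 repressed and from -0.11 to 0.0545 without 1 wild-type array. That of pst1 reversed to -0.00308 with wild-type replicates 1 to 5 only and passed with replicates 6 to 8 only (1.82, adjusted p = 0.0189). That of pst2 reversed to 0.11 without background correction, 0.12 with spot set 2, 0.63 with wild-type replicates 6 to 8 only, 0.0628 with the random block, 0.39 without the arrays that stand apart and 0.000456 with plate names exchanged back. It ranged from -0.79 to 0.79 and from -0.23 to 0.10 without 1 array. That of clr6 ranged from -0.81 to 0.0445 without 1 array labelled pst3 repressed.

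The 1 gene of the wild-type ratios became 0 with median centring, without background correction, with replicates 2 to 5 alone, with the authors' values, whose columns are not turned alike and so are no check of stability, and without any 1 array (lowest 0, highest 0), 36 with replicates 6 to 8 alone and 17 with the print as a block. The 86 Pst3-GFP regions became 642 with normexp, 35 and 0 with spot sets 1 and 2, 0 with background subtracted, 18 with normexp and loess and 0 with the authors' values. Beads regions numbered 1199 IGRs and 1597 ORFs, and 624 and 621 with loess. The correlation of the IGR experiments ranged from -0.0688 to 0.267 without 1 array. The expression difference of genes beside the IGRs with the highest Pst3-GFP ratio was -0.0366 for the top 10% and ranged from -0.0140 to 0.12 without 1 array. That of ORFs was 0.0816 with the beads ratio turned.

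For hst4D over hst2D the counts were 17 IGRs and 32 ORFs with normexp and 9 and 5 at 1.5-fold. Against wild type, hst2D IGRs numbered 216 with normexp, 3 with loess and 304 at 1.5-fold, hst4D IGRs 211, 5 and 285, hst2D ORFs 251, 16 and 246, and hst4D ORFs 236, 12 and 250. In the authors' values, counted by spot without the rule on both spot sets, 2798 IGR and 2082 ORF spots differed at least 2-fold for hst4D over hst2D, 3369 and 2263 for hst2D and 3286 and 2301 for hst4D against wild type.

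Planned but not run were the pst3 coefficient against 0, the authors' values for the pst3 test and lists, Pst3-GFP lists, agreement, binding and beads results, a joint fit, leave-one-out and IGR spot sets for the beads slide, and leave-one-out for the 2 input arrays and their lists, where 1 array leaves no residual degrees of freedom.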

Other observations

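The arrays labelled pst3 repressed had a rank correlation of 0.854 with each other and mean rank correlations of 0.53 and 0.57 with the wild-type arrays. Among wild-type arrays the mean rank correlation with the others ranged from 0.544 for replicate 3 to 0.754 for replicate 4. The 2 deposited spot sets of channel 7-3 on the IGR probes of the beads slide were 1 identical pair and were used once.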
